A study of Mus musculus with 12 samples.

How the data were processed

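Hippocampal tissue was flash frozen and made into paired-end Illumina libraries, per the labels' protocols. The authors deposited 1 table of counts per library, with whole-number read counts for 24499 gene rows named by symbol and 5 further rows for reads given to no gene. The submitters' processing notes name HISAT2 2.1.0, HTSeq 0.9.1, DESeq2 (version not given) and the build mm10. The annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes may not be separated. The rows for no gene were left out of library sizes and tests: of all rows, reads aligned to several places made up 15.0 to 20.0%, reads outside genes 7.92 to 10.5%, unaligned reads 3.18 to 6.29%, low-quality alignments 2.06 to 3.11% and ambiguous reads 1.21 to 1.42%. Reads from genes with close copies, such as Rpl7a, Sumo2, Gm10591 and the globins, are lost or split by such counting.

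Gene counts summed to between 24891407 and 33477712 per library. Mitochondrial mRNAs took 6.12 to 9.84% of them and the 10 most abundant genes 8.23 to 11.9%. Sequenced fragments without molecular identifiers are not independent molecules, so depth bounds counting error only. Groups and replicate numbers were taken from the labels, 3 groups with 4 libraries each. The labels name mice, and that each library came from a separate mouse was taken from them. Counts of every library pair differed by more than sampling noise, with a chi-square per degree of freedom of at least 15.0 over genes with at least 20 counts.

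Fits were made in R 4.3.3. Counts were filtered with filterByExpr by group, leaving 16257 genes, scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest) over all 12 libraries with group means only. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 22.1%. CPM values are counts scaled to the TMM-adjusted library total. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Gene lists with at least 5 tested genes, 37 in all, were fixed before the data were examined. They cover glutamate receptors and their signalling, the clock, sleep loss, neuronal activity, stress, synapses and channels, mitochondria and ribosomes, and markers of cell types and neighbouring regions. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with its preset correlation of 0.01, adjusted over the 37 lists, and again with an estimated correlation. None of the 31 list calls over the 4 comparisons held with the estimated correlation. Single genes were also adjusted over their own list alone, separately for each of the 37 lists and 4 comparisons. In this way 1, 1, 1 and 3 genes passed. That adjustment does not count the number of lists and comparisons, so such passes may arise by chance.

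The genes named follow a rule fixed then as well. It takes Grm1, the 10 called genes with the smallest p in each direction, or the 5 with the smallest p where fewer than 5 were called, with a mean log2 CPM of at least 0. It adds up to 4 members of each called list and up to 2 of other lists, by smallest p, the 5 in each direction for the pooled comparison, and up to 10 genes with a small p in both lines. Because edgeR called none, the last part was applied to genes with an unadjusted p under 0.05 in both lines. The genes named for the fits without the least similar libraries and for the replicate-number contrast were chosen after their values were seen. Coordinates are from GENCODE M21, whose assembly is mm10. Of the 24499 gene rows, 23688 matched a symbol in it.

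On simulated counts with 200 changed genes, edgeR recovered 41.8% of 1.5-fold, 71.6% of 2-fold and 93.9% of 4-fold changes for Grm1b-R889W against WT over 16139 genes. It recovered 43.3, 74.6 and 98.5% for Grm1-S458A against WT over 16129 genes, and 37.3, 77.6 and 98.5% between the mutant groups over 16133 genes. Each gene was drawn on its own, without differences shared by many genes of a library. With 200 changed genes the adjusted threshold is also easier to pass than for a lone changed gene. These shares thus do not give the power to find a lone changed gene in the real libraries. Alternatives fixed before were other size factors, 2 other filters, DESeq2 1.42.0, limma voom, fits of only the groups compared, the replicate number as a block, leaving out each library, a threshold of 0.1 and the estimated correlation. Added after seeing the data were a fit without the 4 least similar libraries, a choroid plexus score as covariate, voom with quality weights, a term for the numbers 1 and 2 against 3 and 4, and fits within each of these. Shared WT libraries were handled with 50 simulations of unchanged groups for the correlation and 20 for the overlap. These drew all 12 libraries, WT included, from a common mean per gene, each gene on its own.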

Results

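RNA was sequenced from the hippocampus of 12 male C57BL/6 mice in 3 groups of 4: wild type (WT), a knock-in labelled Grm1b-R889W and a knock-in labelled Grm1-S458A. Grm1 encodes a group I metabotropic glutamate receptor, a receptor that couples glutamate release to phospholipase C signalling. The labels state that both lines were made with CRISPR/Cas9, and that the mice were 5 months old, singly housed under 12 h of light and 12 h of dark, and sampled at ZT20, which is counted in hours from lights on. The libraries held between 24891407 and 33477712 gene counts, and 16257 genes had enough counts to be tested. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had at least 397 counts in each library, and Xist, which is transcribed from the inactive X chromosome, had between 1 and 34 counts.

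The first comparison asks how the Grm1b-R889W hippocampus differs from WT. Genes typical of the choroid plexus, the epithelium that secretes cerebrospinal fluid, were lower as a group, and so were markers of blood, vascular cells, astrocytes and microglia. Genes of the synaptic vesicle cycle, voltage-gated channels and a mixed list of cytosolic heat shock and cold-inducible genes were slightly higher as groups. These group calls came from limma camera with a preset correlation, and none held with an estimated correlation. The level of Grm1 itself was 37.4 ± 5.91 CPM (SD, n = 4) in Grm1b-R889W and 33.2 ± 4.01 CPM (SD, n = 4) in WT. Its log2 fold change was 0.17 ± 0.126 (SE), which did not pass (edgeR adjusted p = 1.0). It was 0.28 without Grm1b-R889W 1, the lowest library of the group, and did not pass there either. Grm1 is a protein-coding gene on chromosome 10 from 10686059 to 11082356 on the minus strand (mm10). Both lines carry a change in the protein, so its RNA level does not check the labels.

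Of single genes, Sfrp5, which encodes a secreted inhibitor of Wnt signalling, had the smallest p value. Its level was 2.20 ± 0.73 CPM (SD, n = 4) in Grm1b-R889W and 6.30 ± 2.01 CPM (SD, n = 4) in WT. The Grm1b-R889W libraries ranged from 1.38 to 3.04 CPM for Sfrp5 and the WT libraries from 4.29 to 9.03 CPM. The log2 fold change of Sfrp5 was -1.52 ± 0.28 (SE), which did not pass in edgeR (adjusted p = 0.73) and passed in DESeq2 (adjusted p = 0.00628). Sfrp5 lies on chromosome 19 from 42197971 to 42202252 on the minus strand. The next genes on the lower side, not called, were Arhgef5 (log2 fold change -0.94 ± 0.226), Npr1, a receptor for natriuretic peptides (-0.73 ± 0.179), Fkbp9 (-0.40 ± 0.0996) and the ribosomal protein gene Rpl7a (-0.58 ± 0.149). On the higher side, also not called, were Eid2b (0.51 ± 0.114), Osbpl5 (0.43 ± 0.12), the transcription factor gene Bcl11a (0.41 ± 0.121), Ankrd45 (0.36 ± 0.108) and Tmem117 (0.67 ± 0.198).

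**Figure D1:**
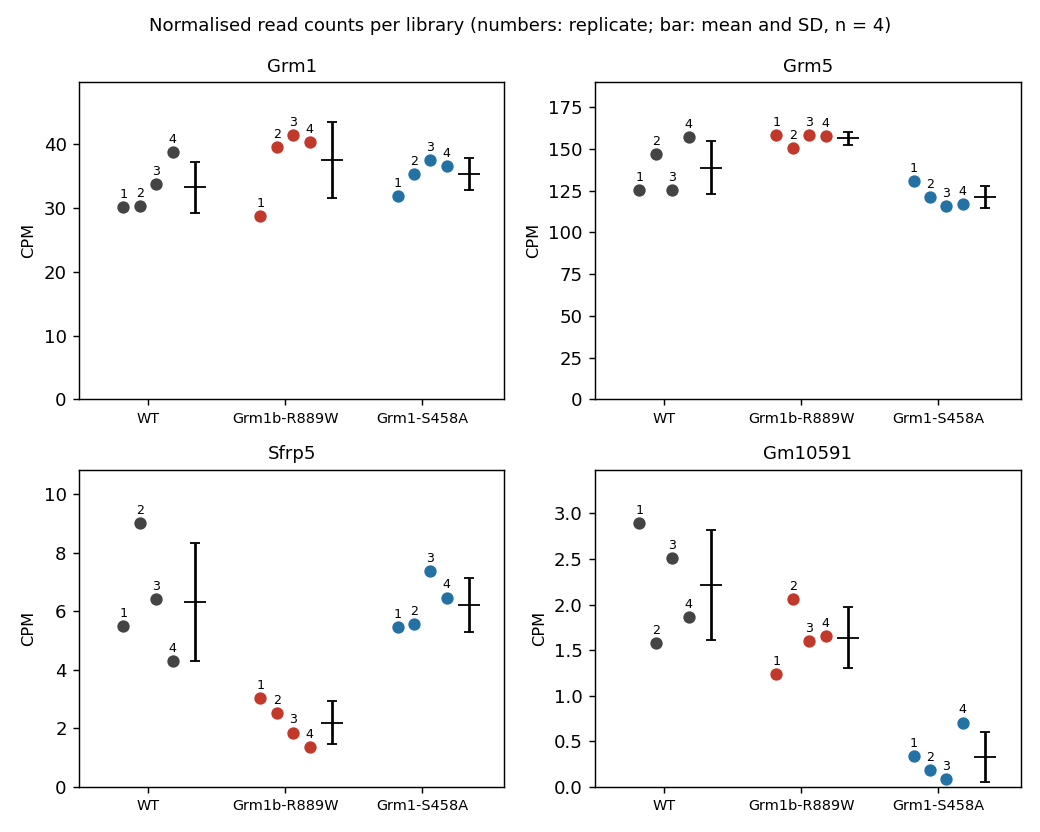
Normalised read counts in CPM (vertical axes) of Grm1, Grm5, Sfrp5 and Gm10591 in each library, with the group mean and SD beside the 4 points of each group. The 4 Grm1b-R889W libraries sit between 1.38 and 3.04 CPM for Sfrp5, below the WT libraries, which start at 4.29 CPM.

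All 17 choroid plexus markers had fold changes below 0 in Grm1b-R889W, with a median log2 fold change of -1.26, and the list was called lower (camera adjusted p = 1.05e-09 with the preset correlation; adjusted p = 0.831 with an estimated correlation). Steap1 stood at -2.00 ± 0.579, Folr1, a folate receptor, at -1.36 ± 0.569, the collagen gene Col8a1 at -1.29 ± 0.502 and the coagulation factor gene F5 at -1.15 ± 0.457, and none of the 17 passed in edgeR. Without WT 2 alone, Folr1 stood at -0.83 and Col8a1 at -0.82. The same markers varied within every group. Ttr, the abundant thyroid hormone carrier of this tissue, ranged from 253 to 15016 CPM over the 12 libraries. The 11 blood markers were likewise all below 0, with a median of -0.58 (camera adjusted p = 0.0088 with the preset correlation; adjusted p = 0.831 with an estimated correlation). The beta-globin gene Hbb-bs was at 437 ± 194 CPM (SD, n = 4) against 871 ± 288 CPM (SD, n = 4) in WT, a log2 fold change of -1.0 ± 0.291, and it was the 1 blood gene that passed when adjusted over the list alone (adjusted p = 0.0355). Alas2, the first enzyme of heme synthesis in red cells, stood at -0.93 ± 0.393, and at -0.53 without WT 1. Globin genes have close copies, so reads may be split between them.

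Vascular markers were lower with a median log2 fold change of -0.15, 15 of 18 below 0, with Pecam1 at -0.35 ± 0.182 (-0.22 without Grm1b-R889W 1). Astrocyte markers had a median of -0.13, all 15 below 0. Slco1c1, a thyroid hormone transporter, stood at -0.38 ± 0.144, and 1 of the 15 had an unadjusted edgeR p under 0.05. Sox9 stood at -0.19 and Slc1a3 at -0.13 (-0.06 without Grm1b-R889W 1). Microglial markers had a median of -0.13, all 15 below 0, with Aif1 at -0.37 ± 0.205 (-0.24 without Grm1b-R889W 4). Synaptic vesicle genes were higher with a median of 0.09, 29 of 33 above 0, among them the active zone gene Erc2 at 0.27 ± 0.0967 and Vamp1 at 0.24 ± 0.115. Voltage-gated channel genes had a median of 0.11, 32 of 35 above 0, with Hcn1 at 0.21 ± 0.109. Kcnh7 went the other way at -0.54 (-0.38 without WT 1). The mixed list of heat shock and cold-inducible genes, named heat shock genes below for short, had a median of 0.08, 20 of 24 above 0. Its heat shock and cold-inducible members were not tested apart. The chaperone genes Hsph1 and Hspa1b stood at 0.27 ± 0.115 and 0.47 ± 0.204, and Hspb8 went the other way at -0.27 (-0.14 without WT 2). The camera adjusted p with the preset correlation was 0.0088 for vascular and astrocyte markers, 0.0172 for microglia and heat shock genes, 0.016 for channels and 0.0002 for vesicle genes. With an estimated correlation each had adjusted p = 0.831.

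Groups tied to the receptor or to time of day were not called in Grm1b-R889W. The 7 metabotropic glutamate receptor genes had camera adjusted p = 0.102, the 33 genes of group I receptor signalling 0.112 and the 31 genes that respond to sleep loss 0.242. The 24 clock genes had a median log2 fold change of 0.02, with 14 above 0 and 10 below. Among them, Grm5, the other group I receptor, stood at 0.17 ± 0.0982, the scaffold gene Homer1 at 0.26 ± 0.111, the circadian transcription factor gene Clock at 0.20 ± 0.106 and Tspan4 at -0.42 ± 0.183. Without Grm1b-R889W 1, Homer1 stood at 0.15 and Tspan4 at -0.64. The 23 genes near Grm1 on chromosome 10 had camera adjusted p = 0.356.

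The test across all genes called 0 genes in Grm1b-R889W against WT with edgeR's quasi-likelihood test and 0 with limma voom, while DESeq2 called 1, Sfrp5. At an unadjusted p under 0.05 edgeR gave 578 genes (222 higher and 356 lower). Evenly spread p values would give 813, and other splits of the same libraries gave a median of 594.5. Leaving out WT 3 moved the number of called lists from 8 to 5, and leaving out WT 4, Grm1b-R889W 1 or Grm1b-R889W 2 moved it to 19, 15 and 16. Without the 4 libraries least similar to the rest (WT 4, Grm1b-R889W 1 and 4, Grm1-S458A 4), a choice made after seeing the data, edgeR called 14 genes lower and camera called 14 lists, but no longer astrocytes (adjusted p = 0.974, with the direction reversed), heat shock genes (0.849) or microglia (0.468). The 14 genes included the choroid plexus genes Ttr (-3.91 ± 0.638), Kcnj13 (-3.15 ± 0.508) and Aqp1 (-2.87 ± 0.438). That fit kept only Grm1b-R889W 2 and 3 of their group, whose mean choroid plexus marker levels were the lowest (scores -1.10 and -2.22). The dropped Grm1b-R889W 1 and 4 had scores of 0.37 and -0.14. These calls thus depend on which libraries were kept. The choroid plexus list was called in 12 of 12 fits that left out 1 library each. The channel list was called in 8 of them, with adjusted p = 0.685 without WT 2, and astrocytes in 10, with adjusted p = 0.542 without Grm1b-R889W 1. Heat shock genes and microglia were called in 9 of them, with adjusted p = 0.233 and 0.385 without Grm1b-R889W 1. Blood was called in 10 (0.307 without Grm1b-R889W 3), vesicle genes in 11 (0.171 without WT 2) and vascular cells in 11 (0.0646 without WT 3). Of these 12 fits, 4 left out a Grm1-S458A library, which is outside this comparison, and each called 8 lists. Those 4 say little on stability. With the choroid plexus score of each library as a covariate, also added after seeing the data, the lists of choroid plexus (adjusted p = 0.978), blood (0.0999), vesicle genes (0.153) and channels (0.826) were not called. Astrocytes (camera adjusted p = 2.94e-08 with the preset correlation), vascular cells (0.000514), microglia (0.00334) and heat shock genes (0.045) were still called with it.

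**Figure D2:**
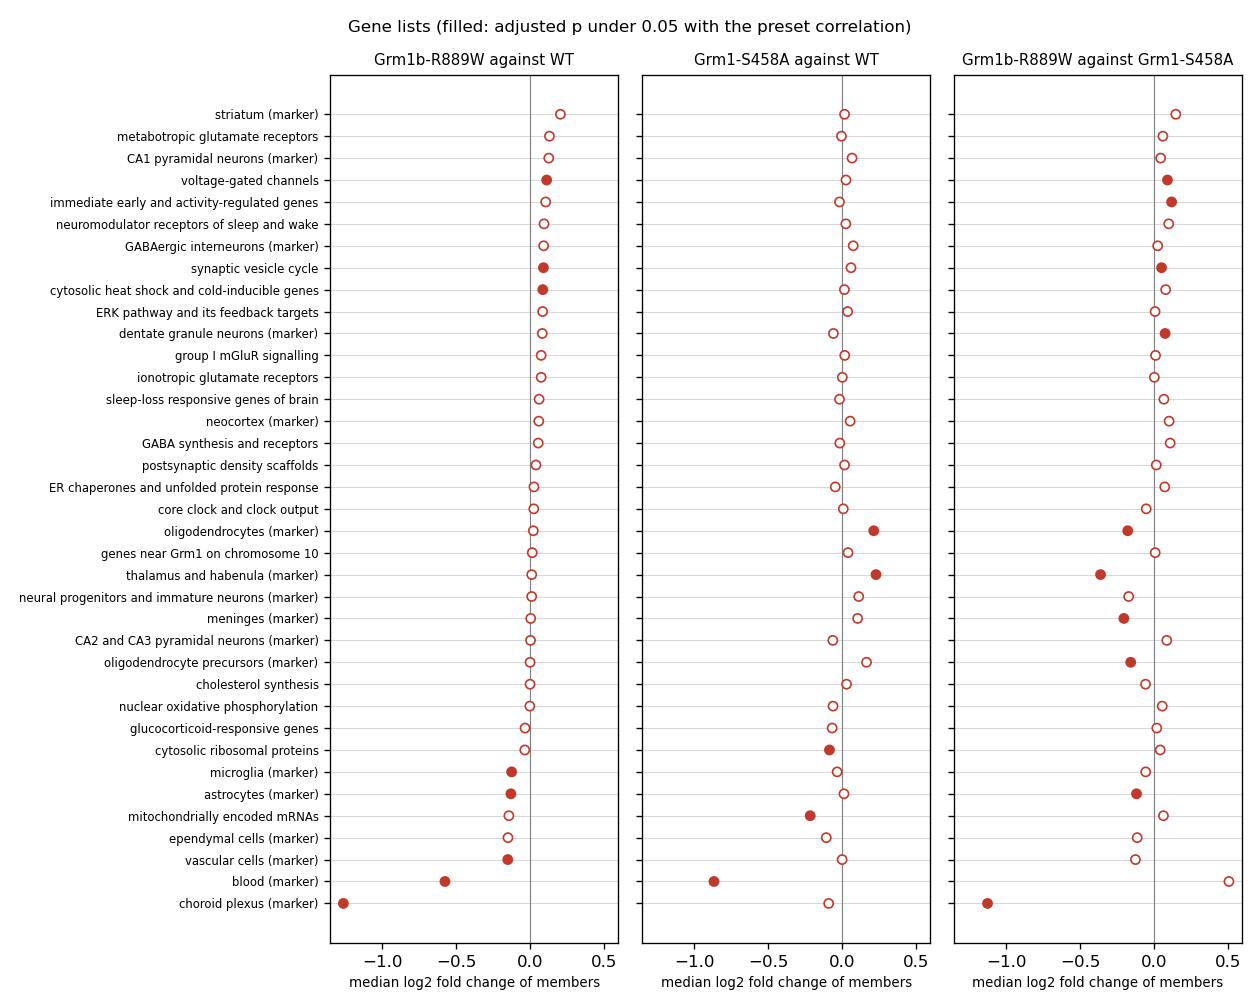
Median log2 fold change of the members of each of the 37 gene lists (horizontal axis) in the comparisons named above the panels, with filled points for lists that camera called with the preset correlation. Choroid plexus markers stand at -1.26 in Grm1b-R889W against WT and at -0.09 in Grm1-S458A against WT.

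The second comparison asks how the Grm1-S458A hippocampus differs from WT. Blood markers were lower as a group, and so were ribosomal protein genes and the mRNAs encoded in the mitochondrial genome. Oligodendrocyte markers and markers of thalamus and habenula, regions next to the hippocampus, were higher as groups. None of these list calls held with an estimated correlation. Grm1 was at 35.3 ± 2.47 CPM (SD, n = 4), a log2 fold change of 0.09 ± 0.126 (SE) against WT that did not pass (edgeR adjusted p = 1.0). It ran from 0.0444 without WT 1 to 0.16 without WT 4.

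The gene with the smallest p was Gm10591, a predicted gene on chromosome 4 from 42612195 to 42612860 on the plus strand. Its level was 0.328 ± 0.272 CPM (SD, n = 4) in Grm1-S458A and 2.21 ± 0.603 CPM (SD, n = 4) in WT. The Grm1-S458A libraries reached at most 0.706 CPM for Gm10591 and the WT libraries at least 1.57 CPM. The log2 fold change of Gm10591 was -2.76 ± 0.558, not called by edgeR (adjusted p = 1.0) and called by DESeq2 (adjusted p = 0.00206). Gm10591 belongs to a cluster of duplicated chemokine genes, so its counts are uncertain. The next genes on the lower side, not called, were the axonemal dynein gene Dnah1 (-0.54 ± 0.147), Rccd1 (-0.72 ± 0.211), the collagen gene Col11a1 (-0.91 ± 0.27) and S100a9, a calcium-binding protein of neutrophils (-1.36 ± 0.408). On the higher side, not called, were Dbp, a transcription factor under direct control of the circadian clock (0.45 ± 0.127), Hnrnpa0 (0.33 ± 0.0995), Sumo2 (1.15 ± 0.347), Rexo4 (0.33 ± 0.099) and Zcchc3 (0.59 ± 0.177). Sumo2 has close copies in the genome, and its level in Grm1-S458A 4 was 67.2 CPM against at most 22.6 CPM in the other libraries of the group. Without that library the log2 fold change of Sumo2 was 0.46.

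The 11 blood markers were all below 0 in Grm1-S458A, with a median log2 fold change of -0.87 (camera adjusted p = 6.44e-08 with the preset correlation; adjusted p = 0.944 with an estimated correlation). Hbb-bs stood at -0.84 ± 0.29, S100a8 at -1.28 ± 0.493 and Alas2 at -0.97 ± 0.394 (-0.58 without WT 1), and 1 blood gene, S100a9, passed when adjusted over the list alone (adjusted p = 0.0434). Oligodendrocyte markers were higher, 14 of 16 above 0 with a median of 0.21 (adjusted p = 6.05e-05 with the preset correlation; adjusted p = 0.944 with an estimated correlation). The myelin genes Mag and Cnp were both at 0.31, with SE of 0.128 and 0.137, and Cldn11 was at 0.25 ± 0.12. Without Grm1-S458A 2, Cnp stood at 0.18 and Cldn11 at 0.14. All 16 thalamus and habenula markers were above 0 with a median of 0.23 (adjusted p = 0.0101 with the preset correlation; adjusted p = 0.944 with an estimated correlation). Of these, Rgs16 stood at 0.64 ± 0.243 and Prkcd, a protein kinase C gene, at 0.44 ± 0.255 (0.28 without WT 2).

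Ribosomal protein genes were lower, 67 of 76 below 0 with a median of -0.09 (camera adjusted p = 0.00014 with the preset correlation; adjusted p = 0.944 with an estimated correlation). Rpl7a stood at -0.47 ± 0.149 (-0.28 without WT 1) and Rps7 at -0.28 ± 0.145. Across all tested genes, the fold changes of this comparison had Spearman correlations of 0.222 with GC content and 0.122 with transcript length. Whether such a bias of the libraries adds to the lower ribosomal protein genes was not tested. Mitochondrial mRNAs had a median of -0.22, 10 of 12 below 0 (adjusted p = 0.0195 with the preset correlation; adjusted p = 0.944 with an estimated correlation), with the complex I subunit gene ND2 at -0.30 ± 0.16. Choroid plexus markers had a median of -0.09 (adjusted p = 0.159). Metabotropic glutamate receptor genes (adjusted p = 0.736), group I receptor signalling genes (0.345), clock genes (0.345) and genes that respond to sleep loss (0.869) were not called. In those groups Grm5 stood at -0.20 ± 0.0983, the phospholipase C gene Plcb4 at 0.46 ± 0.197 and the clock gene Per3 at 0.24 ± 0.132.

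The test across all genes called 0 genes in Grm1-S458A against WT with edgeR and 0 with limma voom, and 1 with DESeq2, Gm10591. At an unadjusted p under 0.05 edgeR gave 400 genes (237 higher and 163 lower). Evenly spread p values would give 813, and other splits of the same libraries gave a median of 470.5. Leaving out WT 3 or Grm1-S458A 2 moved the number of called lists from 5 to 3, and leaving out the 4 least similar libraries moved it to 9. Blood and oligodendrocyte markers were called in 12 of 12 fits that left out 1 library each. Ribosomal proteins were called in 10 (adjusted p = 0.287 without Grm1-S458A 3), thalamus and habenula in 10 (0.205 without Grm1-S458A 2) and mitochondrial mRNAs in 7 (0.343 without Grm1-S458A 3). Of these 12 fits, 4 left out a Grm1b-R889W library, which is outside this comparison, and each called 5 lists. Those 4 say little on stability.

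**Figure D3:**
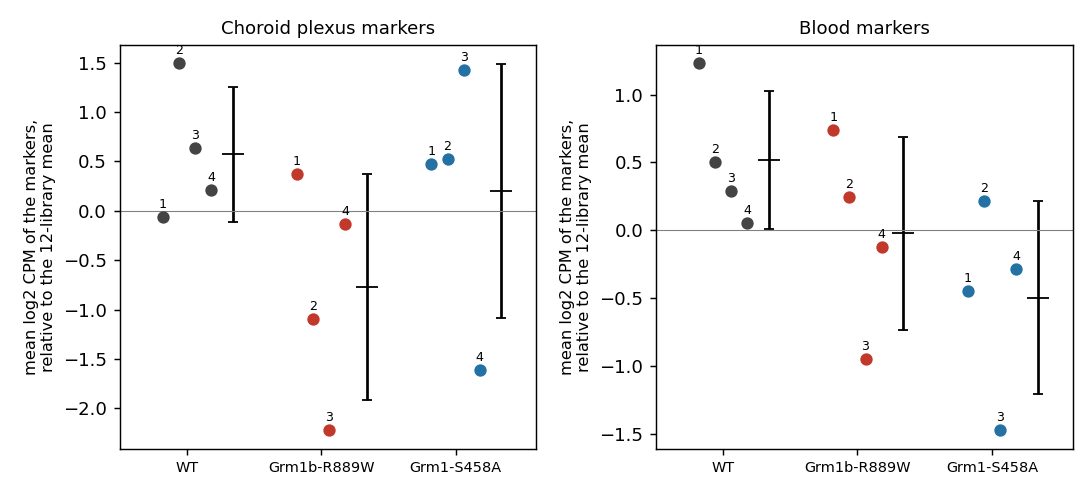
Mean log2 CPM of the choroid plexus markers (left) and blood markers (right) in each library, relative to the mean of the 12 libraries, with the group mean and SD beside the points. The choroid plexus score runs from -2.22 to 0.37 in Grm1b-R889W and from -1.61 to 1.43 in Grm1-S458A, so the groups overlap.

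The third comparison sets the mutant groups against each other. Choroid plexus markers were lower in Grm1b-R889W than in Grm1-S458A, and so were markers of oligodendrocytes, their precursors, astrocytes, meninges, and thalamus and habenula. Voltage-gated channels, synaptic vesicle genes, dentate granule neuron markers and immediate early genes, which neurons induce on activity, were higher. As above, none held with an estimated correlation (adjusted p = 0.824 with an estimated correlation for each of the 10 lists). Grm1 differed by a log2 fold change of 0.08 ± 0.126 (edgeR adjusted p = 0.998), and by 0.20 without Grm1b-R889W 1.

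Sfrp5 again had the smallest p, with a log2 fold change of -1.50 ± 0.28 that did not pass in edgeR (adjusted p = 0.848) and passed in DESeq2 (adjusted p = 0.0095). Its level in Grm1-S458A was 6.21 ± 0.908 CPM (SD, n = 4). Also lower and not called were Nckap5 (-1.01 ± 0.24), Ltbp3, which binds latent TGF-beta (-0.48 ± 0.116), Kif26a (-0.63 ± 0.161) and Tapbp (-0.38 ± 0.0991). Higher and not called were Gm10591 (2.32 ± 0.555), Pkp2, a desmosome gene (0.54 ± 0.139), Pcdh20 (0.38 ± 0.0981), Gm14322 (0.75 ± 0.195) and B3galt2 (0.43 ± 0.112). Grm5 stood at 0.37 ± 0.0984, with 156 ± 3.70 CPM (SD, n = 4) in Grm1b-R889W and 121 ± 6.86 CPM (SD, n = 4) in Grm1-S458A. It was the 1 metabotropic receptor gene that passed when adjusted over the list alone (edgeR adjusted p = 0.0117), and over all genes it did not pass (adjusted p = 0.998).

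All 17 choroid plexus markers were below 0 with a median log2 fold change of -1.13 (camera adjusted p = 9.6e-05 with the preset correlation), among them Steap1 at -1.69 ± 0.577 and Slc4a5, a bicarbonate transporter gene, at -1.37 ± 0.607 (-0.87 without Grm1-S458A 3). Oligodendrocyte markers had a median of -0.18 (adjusted p = 0.00139), with Mobp at -0.39 ± 0.131 and Mbp, a main protein of myelin, at -0.41 ± 0.138. Thalamus and habenula markers had a median of -0.36 (adjusted p = 0.00711), with Zic1 at -0.46 ± 0.208 (-0.28 without Grm1b-R889W 3). Meningeal markers had a median of -0.20, with Igf2 at -0.48 ± 0.243 (-0.27 without Grm1b-R889W 3). Astrocyte markers had a median of -0.12, with Gfap at -0.20 ± 0.161 (-0.0651 without Grm1b-R889W 1), and precursor markers a median of -0.16, with Matn4 at -0.26 ± 0.126. Immediate early genes had a median of 0.12, 26 of 36 above 0, with Junb at 0.33 ± 0.132 and Ptgs2 at 0.39 ± 0.161. Channel genes had a median of 0.09, 27 of 35 above 0, with the sodium channel gene Scn3a at 0.38 ± 0.144. Vesicle genes had a median of 0.05, with Sv2b at 0.30 ± 0.107, and dentate granule markers a median of 0.07, with the calcium channel gene Trpc6 at 0.42 ± 0.16. The adjusted p with the preset correlation was 0.0113 for channels, 0.0115 for dentate granule markers, 0.0124 for immediate early genes and 0.0287 for meninges. It was 0.0185 for astrocytes, vesicle genes and precursors, and each of these lists had adjusted p = 0.824 with an estimated correlation.

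Between the mutant groups edgeR called 0 genes and limma voom 0, and DESeq2 called 1, Sfrp5. At an unadjusted p under 0.05 edgeR gave 695 genes (299 higher and 396 lower). Leaving out Grm1b-R889W 3 moved the number of called lists from 10 to 6, and without the 4 libraries least similar to the rest camera called 3 lists and edgeR called 16 genes lower, among them Ttr (-3.80 ± 0.634). Of the 10 lists above, choroid plexus and channels were still called there, and the others had adjusted p from 0.0626 for meninges to 0.872 for oligodendrocytes, with astrocytes reversed. That fit dropped Grm1-S458A 4, whose choroid plexus score was the lowest of its group (-1.61). It kept Grm1b-R889W 2 and 3 (-1.10 and -2.22) and dropped 1 and 4 (0.37 and -0.14). The choice of libraries thus widened the choroid plexus difference. Over the fits that left out 1 library each, choroid plexus and oligodendrocyte markers were called in 11 of 12, with adjusted p = 0.113 without Grm1b-R889W 3 and 0.0653 without Grm1b-R889W 1. The other lists were called in 8 to 10 of them, astrocytes (adjusted p = 0.698 without Grm1b-R889W 1) and meninges (0.574 without Grm1b-R889W 4) in 8. Of these 12 fits, 4 left out a WT library, which is outside this comparison, and each called 11 lists. Those 4 say little on stability.

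The last comparison pools both mutant groups against WT. Blood markers (median log2 fold change -0.74), choroid plexus markers (-0.67), ribosomal protein genes (-0.06), vascular markers (-0.06), microglial markers (-0.07) and mitochondrial mRNAs (-0.17) were lower. Synaptic vesicle genes (0.08) and oligodendrocyte markers (0.11) were higher. The pooled value does not show that both lines changed. Choroid plexus markers had a median of -1.26 in Grm1b-R889W against WT and -0.09 in Grm1-S458A against WT. Oligodendrocyte markers had 0.02 and 0.21 in that order. Hbb-bs was the 1 blood gene and Rpl7a the 1 ribosomal protein gene that passed when adjusted over the list alone (edgeR adjusted p = 0.0163 and 0.0486). Nxph4, a neocortex marker, also passed over its list alone (edgeR adjusted p = 0.0479), in a list that was not called. The camera adjusted p with the preset correlation ran from 1.46e-06 for blood to 0.039 for microglia and mitochondrial mRNAs, and each list had adjusted p = 0.82 with an estimated correlation. Single genes with the smallest p, none called, were Rpl7a (-0.53 ± 0.126), Rnaset2a (-1.04 ± 0.272), Hbb-bs (-0.92 ± 0.243), Gm10591 (-1.60 ± 0.430) and Zfand1 (-0.53 ± 0.147) on the lower side. Gm10591 was lower mainly in Grm1-S458A, with a mean of 0.328 CPM against 2.21 in WT and 1.64 in Grm1b-R889W. Rnaset2a stood at -0.59 without WT 3, and Rpl7a at -0.34 without WT 1. On the higher side they were Eid2b (0.40 ± 0.0998), Tmem117 (0.66 ± 0.176), Nxph4 (0.99 ± 0.288), Elp6 (0.53 ± 0.158) and Zfp108 (0.66 ± 0.197). The test called 0 genes with edgeR, 0 with limma voom and 0 with DESeq2, and edgeR gave 424 genes at an unadjusted p under 0.05. Leaving out WT 2, WT 3 or Grm1-S458A 3 moved the number of called lists from 8 to 5, 4 and 5, and leaving out WT 4 or Grm1b-R889W 2 moved it to 17 and 15. Without the 4 least similar libraries it was 17, and microglia (adjusted p = 0.179) and mitochondrial mRNAs (0.674) were not called. Over the fits that left out 1 library each, blood and choroid plexus were called in 12 of 12 and vesicle genes in 11. Ribosomal proteins, oligodendrocytes and vascular cells were called in 7, and microglia and mitochondrial mRNAs in 6. With the choroid plexus score as a covariate, choroid plexus (camera adjusted p = 0.994), oligodendrocytes (0.479) and vesicle genes (0.212) were not called.

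The fold changes of the mutant groups against WT had a Pearson correlation of 0.472 across genes, which are not independent replicates. Both comparisons use the same WT libraries. Simulations that drew all 12 libraries, WT included, from a common mean per gene gave 0.5 on average, from 0.477 to 0.537. They drew each gene on its own, so that range leaves out that genes vary together. The observed value had a jackknife SE of 0.198 over the fits that left out 1 library each. The covariance was 0.044 against 0.0522 in the simulations. With the WT libraries split into pairs, 1 pair for each line, the correlation was -0.0269 on average. No gene was called by edgeR in both lines (0 genes), and 66 had an unadjusted p under 0.05 in both in the same direction. Independent lists of the observed lengths give 6.81, a value that ignores the shared WT libraries, so it does not show an excess. Simulated unchanged groups gave 162.6, but from longer lists, with 786.2 genes at that p on average, so this value cannot be set directly against the 66. Tmem117 (0.67 and 0.66), Rpl7a (-0.58 and -0.47), Hbb-bs (-1.0 and -0.84) and Nxph4 (0.93 and 1.04) were among those 66.

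With the groups as terms, edgeR called 818 genes between libraries numbered 3 and 4 and those numbered 1 and 2, a contrast chosen after seeing the data. Pairing the Grm1-S458A libraries otherwise, with the WT and Grm1b-R889W pairs kept, gave up to 1191 genes, so the Grm1-S458A libraries were not shown to follow the number. Of the 818, 402 were higher in numbers 3 and 4, among them the calcium channel gene Cacna1i (0.57 ± 0.081) and the active zone gene Erc1 (0.53 ± 0.0798). The other 416 were lower, among them the globin gene Hba-a2 (-1.45 ± 0.17), Sec61g (-0.95 ± 0.155) and the ribosomal protein gene Rpl41 (-0.69 ± 0.113). With this term in the model edgeR called 0 genes in each genotype comparison, with 761, 541, 923 and 540 genes at an unadjusted p under 0.05 in the order given above. Within numbers 1 and 2 alone it called 0 genes in each, with 792, 712, 1355 and 633 at that p, and within numbers 3 and 4 alone 0 in each, with 654, 678, 1164 and 459.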

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

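The tests of the choroid plexus pattern, of the counts of genes over other splits, of molecules and depth behind the spread, and of the replicate numbers and transcript length were chosen after the result was seen, while the splits of list counts, the odd counts and GC content were tested as written in advance.

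The lists whose effect differed between the lines, by the direct camera test of Grm1b-R889W against Grm1-S458A with the preset correlation, were choroid plexus (adjusted p = 9.6e-05), oligodendrocytes (0.00139), thalamus and habenula (0.00711), voltage-gated channels (0.0113) and dentate granule neurons (0.0115). Immediate early genes (0.0124), astrocytes, synaptic vesicle genes and oligodendrocyte precursors (0.0185 each) and meninges (0.0287) followed. None held with an estimated correlation (smallest adjusted p = 0.824 with an estimated correlation).

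Other splits of the same libraries do not exclude chance for the counts of lists. For genes called by edgeR the real count was 0 in each comparison, which every split reaches by construction (35 of 35 in each comparison of 4 libraries with 4, and 100 of 100 drawn splits in the pooled one), so the number called says nothing on chance. At an unadjusted p under 0.05 the real counts of 578, 400, 695 and 424 were reached by 18, 24 and 13 of 35 splits and 88 of 100, with medians of the other splits of 594.5, 470.5, 585 and 634, so chance is not excluded for these counts. DESeq2 called 1, 1, 1 and 0 genes and limma voom 0 in each. The highest other split called 1794 genes for Grm1b-R889W with WT and 1 in each of the other comparisons. For lists, 26 of 35 splits called at least the 8 of Grm1b-R889W against WT (highest other 19) and 31 of 35 at least the 5 of Grm1-S458A against WT (highest other 18). Between the mutant groups 18 of 35 called at least 10 (highest other 23), and in the pooled comparison 66 of 100 called at least 8 (highest other 19). The split with 1794 genes set libraries 3 and 4 of both groups against 1 and 2. It calls many more genes than the real split, which points to a structure of these 8 libraries, but it is the highest of the splits, and the same division of the Grm1-S458A and WT libraries called 0 genes with edgeR, with 927 at an unadjusted p under 0.05 and no other tool run on it. The same division of the 2 mutant groups called 1 gene with edgeR, with 2045 at that p, above the median of 585 and below the highest other split at 2315.

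The first pattern is the lower level of choroid plexus markers in Grm1b-R889W than in WT. Uneven carry-over of choroid plexus in dissection may account for it. The first component held 94.2% of the variance of the 17 markers within groups. The score ranged over 1.56 within WT and 3.03 within Grm1-S458A, against a group difference of -1.34. Markers of 1 tissue move together whatever alters its amount, so the shared component cannot set carry-over apart from genotype. An effect of genotype stays open, since the exact permutation test of the score gave p = 0.114, two-sided, where 0.0286 is the smallest that 4 against 4 libraries allow. With the score as a covariate the list had adjusted p = 0.978, a setting that removes the score itself and so cannot separate these explanations.

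The second pattern is a spread of low-count genes beyond counting error. The variance was 8.09 times the mean at 5 to 10 counts and 9.20 times at 20 to 50 counts, a ratio of 1.14, which is consistent with few distinct molecules behind the reads. Counting of both mates of a pair is argued against, since 51.1% of counts from 5 to 50 were odd. Library depth as the whole cause is argued against, because 2 of the 4 libraries with the most zeros, WT 4 (29.5 M gene counts) and Grm1b-R889W 1 (28.7 M), lay above the median of 28.4 M, although the shallowest library, Grm1b-R889W 4, had the most zeros. Genotype was not tested for this pattern, and each group holds 1 of the libraries numbered 4, with 3.49% zeros in WT, 4.04% in Grm1b-R889W and 2.62% in Grm1-S458A among genes of 20 to 50 counts.

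The third pattern is the 818 genes that differed between libraries numbered 1 and 2 and those numbered 3 and 4. Of 27 splits of each group into pairs, 2 called as many (highest other 1191), and 2 of the 100 splits run in all, but this split was singled out because it had called many genes, so its rank carries no weight against chance. A length bias of the libraries may be part of it: the Spearman correlation across genes of transcript length with the fold change was 0.357, and 0.345 without ribosomal and respiratory genes, although genes are not independent replicates. For GC content it was 0.178, between the bounds set in advance, so a GC bias stays open. In the 4 genotype comparisons, in the order given above, the correlation with GC content was -0.00675, 0.222, -0.207 and 0.125. Genotype is balanced over the numbers, and no biological explanation was tested.

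Chance alone gives about 24.15 single libraries far from the other 3 of their group among the 483 groups of values tested, and 26 were found. In Grm1b-R889W 1 these were Grm1 (28.6 CPM, the others 39.54 to 41.3), Rexo4 (30.9 CPM), Grm4 (13.1 CPM), Lrrc55 (9.25 CPM) and the score of metabotropic glutamate receptors (-0.0862). In Grm1b-R889W 2 they were Grm5 (151 CPM), Prkcd (50.1 CPM) and Tnnt1 (5.18 CPM), and in Grm1b-R889W 3 Sox9 (80.4 CPM), Sumo2 (10.6 CPM), Mobp (975 CPM) and Mbp (9693 CPM). In Grm1-S458A 1 they were Hsph1 (133 CPM), Scn3b (151 CPM), Zic1 (44.5 CPM), Nxph4 (3.08 CPM) and the score of neuromodulator receptors (-0.14). Grm1-S458A 3 had the highest depth of its group (3.26e+7 gene counts), and Grm1-S458A 4 stood apart for Sumo2 (67.2 CPM) and Pkp2 (19.4 CPM). Of the WT libraries, WT 1 stood apart for Mobp (1027 CPM) and Col1a2 (44.5 CPM) and WT 3 for Olig1 (232 CPM) and the score of progenitors and immature neurons (-0.29). WT 4 stood apart for the scores of CA2 and CA3 neurons (0.12) and of thalamus and habenula (0.20).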

How the results depend on the processing

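The fits without the 4 least similar libraries, with the choroid plexus score, with quality weights and by replicate number were chosen after the data were seen. Counted once per comparison and setting, 3689 values of named genes kept their direction and side of the threshold, 8 passed only in a setting and 18 reversed. No gene passed in the main edgeR fit, so keeping that side says little. Counted likewise, 454 list calls held, 132 were lost and 3 reversed, and none held with the estimated correlation.

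DESeq2 called 1 gene in Grm1b-R889W against WT, 1 in Grm1-S458A against WT and 1 between the mutant groups. With an estimated correlation camera called 0 lists in each comparison (8, 5, 10 and 8 with the preset). Without the 4 least similar libraries edgeR called 14 genes in Grm1b-R889W against WT and 16 between the mutant groups, and camera 14, 9, 3 and 17 lists. That fit kept only Grm1b-R889W 2 and 3 of their group, which had its lowest choroid plexus scores. There Sox9 (0.10) in Grm1b-R889W against WT, ATP6 (0.0139) in Grm1-S458A against WT, and Gfap (0.0374) and C1ql1 (0.0116) between the mutant groups reversed, as did astrocytes in Grm1b-R889W against WT (camera adjusted p = 0.974) and between the mutant groups (0.742). With the choroid plexus score Folr1 (0.0625) and the choroid plexus list (0.978) reversed in Grm1b-R889W against WT, since the score holds their own values. In numbers 1 and 2 alone Per3 (-0.0320) and ATP6 (0.40) in Grm1-S458A against WT reversed, and between the mutant groups Lct (-0.0942), Igf2 (0.0691), Col1a1 (0.23), Col1a2 (0.30) and Zic1 (0.0763). In numbers 3 and 4 alone Tac2 (-0.30) in Grm1-S458A against WT reversed, and between the mutant groups Gfap (0.0122), Ntsr2 (0.15), Olig1 (0.0375), C1ql1 (0.0361) and Tac2 (0.0280). For the other reversals the cause was not tested. Splitting the WT libraries moved the correlation of the lines from 0.472 to -0.0269 because the shared controls were removed. Leaving out 1 library at a time gave 0 genes throughout in edgeR, 5 to 19, 3 to 6, 6 to 15 and 4 to 17 lists, and a correlation of 0.405 to 0.565. It moved 23 of 49, 13 of 36, 23 of 56 and 2 of 10 named genes by over 1.5 times.

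By correlation the replicate numbers gave little sign of pairing. Same-numbered libraries had correlations of deviations from -0.0432 to 0.114, 1 of 12 pairs above 0.1, and 6 of 24 best matches were to the own number. In each group, though, library 4 had the fewest genes with a count (16868 in WT, 16702 in Grm1b-R889W and 16915 in Grm1-S458A). A factor shared by same-numbered libraries is thus not excluded. With the number as a replicate block edgeR called 1 gene, Hbb-bs, in Grm1b-R889W against WT (adjusted p = 0.0345) and 1, Hbb-bs, in the pooled comparison (0.0129). What depth, molecules per library and differences between mice each add to the spread of low-count genes was not separated.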

Other observations

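Hypotheses on these values were not tested further, and the number-term values below were computed after the result was seen. Pyramidal neuron markers of CA1 had a median log2 fold change of 0.12 in Grm1b-R889W against WT and 0.07 in Grm1-S458A against WT (camera adjusted p = 0.0891 and 0.305, not called), and GABAergic interneuron markers 0.09 and 0.07 (0.125 and 0.298). Genes of the ERK pathway, which group I receptors can drive, had medians of 0.08 and 0.04 (0.0511 and 0.298). Ionotropic glutamate receptors (0.174 and 0.59), postsynaptic scaffolds (0.215 and 0.512), GABA genes (0.242 and 0.567), cholesterol synthesis (0.501 and 0.613), glucocorticoid-responsive genes (0.525 and 0.298), the unfolded protein response (0.525 and 0.329) and nuclear oxidative phosphorylation (0.921 and 0.222) were not called. Markers of neocortex (0.174 and 0.299), striatum (0.361 and 0.860), ependymal cells (0.120 and 0.298), CA2 and CA3 (0.844 and 0.329) and progenitors (0.525 and 0.215) and neuromodulator receptors (0.310 and 0.911) were not called either.

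In the contrast of libraries numbered 3 and 4 with 1 and 2, nuclear oxidative phosphorylation genes (median log2 fold change -0.38) and ribosomal proteins (-0.27) were lower in numbers 3 and 4 (camera adjusted p = 2.16e-22 and 2.32e-20 with the preset correlation; adjusted p = 0.319 with an estimated correlation for both). Postsynaptic scaffolds (0.29) and voltage-gated channels (0.22) were higher (adjusted p = 2.05e-09 with the preset correlation for both; adjusted p = 0.319 with an estimated correlation for both). Cell markers were also among the lists called with the preset correlation. Blood (-0.76, camera adjusted p = 3.08e-05), meninges (-0.34, 0.00336) and choroid plexus (-0.30, 0.0304) were lower in numbers 3 and 4. Astrocytes (0.20, 0.00128) and CA1 neurons (0.25, 0.00849) were higher. With an estimated correlation none of these held. Transcripts called higher had a median length of 5745.5 bases and those called lower 1228.5 bases. Among transcripts under 1 kb the median was -0.31, with 1 called higher and 143 lower, and over 8 kb it was 0.14, with 101 higher and 1 lower.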
